A study of Mus musculus with 2 samples.

How the data were processed

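The samples were 2 sequencing libraries of single cells from 7-day cultures of mouse bone marrow haematopoietic stem cells. Per the labels' protocols the cells were processed with a modified Smart-seq2 with enrichment of 3' ends and sequenced on an Illumina HiSeq. Per the submitters' processing notes TopHat and HTSeq were used with mm10; their versions, settings and roles are not given in the sources used here. The deposited values are raw UMI counts per gene and cell barcode, not normalized by the authors. Whether counting used strand is not given, so antisense genes and their partners cannot be told apart.

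The authors' deposited cell table gave the library and the cytokines of each cell. It listed 139 cells. The count table had 192 columns, and the 53 columns that the cell table does not list were not used. The table had 53379 rows. Symbols, coordinates and gene types came from GENCODE mouse release M21 on GRCm38, the assembly that mm10 names, matched on the gene identifier without its version. A symbol was found for 53274 rows, and the 105 others held 0.0237% of the UMIs. Coordinates are 1-based.

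Cells with at least 500 detected genes were kept. This left out 5 cells, with 54 to 514 UMIs, and kept 134. No doublet caller was run. Per the labels' protocols a micromanipulator was used to pick single cells into lysis buffer. Counts were summed over the cells of a condition and divided by the condition's total UMIs. The ratio of 2 conditions has an exact conditional binomial 95% interval, and a cell share has an exact Clopper-Pearson interval. These cover counting error only, not variation between cells, cultures, animals or libraries. A gene at 0 was compared with a floor of 3 counts over the condition, which is 0.782 CPM in SCF, 0.407 in SCF+TPO and 0.247 in SCF+G-CSF.

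The 25 gene lists, the rule for named genes, the main settings and most alternatives were fixed before the data were examined. A list's ratio is that of its summed UMIs. Members with at least 30 UMIs over both conditions counted as measured, and as higher or lower where the ratio exceeded 1.5-fold with an interval that excluded 1. The median log2 ratio of measured members, with 0.5 counts added, was placed among 10000 random lists of equal size matched on mean expression in 20 bins. Random genes were drawn independently, so the percentiles ignore that members of a list can vary together between cells. They are not tests of a difference between conditions. The sex-linked list was kept out of counts of lists over 1.5-fold. Named genes were, per comparison, the 12 higher and 12 lower genes ranked by the interval bound nearest 1. They needed at least 100 UMIs, a UMI in at least 25% of the cells of the higher condition, and a ratio of at least 2 that held without the cell with most of its UMIs. Mitochondrial and sex-linked genes were left out of that ranking. Kit, Csf3r, Mpl, Socs2, Socs3, Cish, Pim1, Procr, Slamf1 and Mecom, and up to 4 abundant members of each list, could be named whatever their values. The text names some of the genes that the rule takes, and other list members as examples chosen after their values were seen.

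For shares of cells with a UMI, each cell was thinned at random to 12127 UMIs, the 10th percentile. This left out 1 SCF, 7 SCF+TPO and 6 SCF+G-CSF cells as too shallow. For clusters, UMIs were scaled to 10000 per cell and log transformed. The 1000 most variable genes, 10 principal components, 10 neighbours and Leiden resolution 1 were used, without mitochondrial and sex-linked genes.

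The ratio step was tested on simulated counts with 200 changed genes. The simulated sums were Poisson draws without variation between cells. The recovery therefore checks the calculation only and cannot show how the intervals perform on real cells. For SCF+TPO over SCF (11593 genes) a simulated fold of 2 was recovered with a median of 1.98 and a fold of 4 with 3.96, and 95.5% of the intervals held the true ratio. Alternatives were TMM factors, median-of-ratios size factors, equal weights for cells, other filters on cells and genes, leaving out the richest cell, thinning, other totals, and the median of members. With equal weights a cell of few UMIs counts as much as a deep cell, so a single UMI in it weighs more. Leaving out pseudogene-rich cells, pseudogenes and predicted genes, or the cell of either condition richest in a named gene, was added after the data were seen. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2, matplotlib 3.10.9, and edgeR 4.0.16 in R 4.3.3 for the TMM factors.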

Results

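Single-cell RNA sequencing measured the transcripts of mouse bone marrow haematopoietic stem cells after 7 days of culture with stem cell factor (SCF, 50 ng/ml) alone, with SCF and thrombopoietin (TPO, 50 ng/ml), or with SCF and granulocyte colony-stimulating factor (G-CSF, 10 ng/ml). SCF is the ligand of the receptor Kit, TPO the ligand of Mpl and G-CSF the ligand of Csf3r. Cultures were started from single cells with the surface phenotype of long-term repopulating stem cells. The authors' table listed 43 cells from SCF, 48 from SCF+TPO and 48 from SCF+G-CSF. After 1 SCF cell and 4 SCF+TPO cells with fewer than 500 detected genes were left out, 42, 44 and 48 cells remained, with 3835796, 7375698 and 12144904 unique molecular identifiers (UMIs). The median was 79377 UMIs per SCF cell (range 10887 to 374748), 118353 per SCF+TPO cell (1664 to 613685) and 221654 per SCF+G-CSF cell (1311 to 765748). Fewer than 2000 genes were detected in 0 SCF, 7 SCF+TPO and 4 SCF+G-CSF cells of those kept. The highest mitochondrial share of a cell's UMIs was 4.71% in SCF, 33.6% in SCF+TPO and 3.84% in SCF+G-CSF. SCF and SCF+TPO cells were pooled in 1 library, and the SCF+G-CSF cells formed another. The table named no animal or culture, so each condition is 1 sample without replicates and no test between conditions was possible. Values are summed UMIs of a condition scaled to its total, in CPM, and ranges in brackets from here on are exact 95% intervals that cover counting error only.

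The comparison of SCF+TPO with SCF asked what TPO adds to SCF within 1 library. Neutrophil primary granule genes were higher in SCF+TPO, and megakaryocyte and interferon response genes were lower. The neutrophil primary granule list stood at 3523 CPM against 1624 in SCF, 2.17-fold (2.11 to 2.23) higher, with 11 of 16 measured members over 1.5-fold higher and 2 lower. The list's most abundant gene over both conditions was Mt1, with 23.7% of its UMIs in SCF+TPO and 19.6% in SCF, where Gstm1 held 37%. Mpo, the myeloperoxidase of the azurophil granule, stood at 568 CPM against 25, 22.7-fold (18.5 to 28.1) higher, and the serine protease gene Ctsg was 20.5-fold (15.7 to 27.3) higher. Ms4a3, expressed in granulocyte and monocyte progenitors, was 28.8-fold (16.8 to 54.4) higher, whereas Gstm1 was 4.23-fold (3.93 to 4.56) lower. The median member of the list lay at percentile 100 of 10000 random lists matched on mean expression. The 5 SCF+TPO cells richest in each gene held 93.6% of the UMIs of Mpo, 97.6% of those of Ctsg and 98.3% of those of the basophil protease gene Mcpt8. Without the SCF+TPO cell richest in each, Ctsg was 13.5-fold and Ms4a3 19-fold higher, and with every cell weighted equally 8.84-fold and 16.7-fold. The SCF to SCF+TPO ratio of Mpo, Ctsg and Ms4a3 was close to the median of a set of SCF+TPO transcripts found at low level in SCF cells. Mpo and Ctsg belong to that set themselves. If that low SCF level is not expression, the folds of Mpo, Ctsg and Ms4a3 are lower bounds. In GRCm38 coordinates Mpo (ENSMUSG00000009350.13) lies on chromosome 11 from 87793581 to 87804413.

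Megakaryocyte genes were 2.56-fold (2.5 to 2.62) lower in SCF+TPO, with 11 of 21 measured members lower and 2 higher, and a median at percentile 0. Pf4, the platelet factor of alpha granules, was 3.9-fold (3.75 to 4.05) lower, Ppbp, another platelet chemokine, 17.1-fold (11.1 to 27.6) lower, and the platelet glycoprotein gene Gp9 8.42-fold (6.78 to 10.5) lower. The higher members were F2r at 1.74-fold (1.48 to 2.04), or 1.18-fold with every cell weighted equally, and Itgb3 at 2.09-fold (1.55 to 2.86), or 1.26-fold without 1 SCF+TPO cell. The TPO receptor gene Mpl stood at 59.2 CPM in SCF+TPO and 350 in SCF, 5.9-fold (5.29 to 6.59) lower, and the SCF receptor gene Kit was 1.51-fold (1.33 to 1.71) lower, or 2.87-fold with every cell weighted equally. After thinning of every cell to 12127 UMIs, Mpl was detected in 11 of 37 SCF+TPO cells (29.7%) and 38 of 41 SCF cells (92.7%), against 61.4% and 95.2% unthinned. Mpl (ENSMUSG00000006389.13) lies on chromosome 4 from 118442415 to 118457513.

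Of the 27 measured stem cell genes, 19 were lower and 2 higher in SCF+TPO, with a median at percentile 0, while their summed share was nearly level, at a ratio of 0.947 (0.931 to 0.963). The transcription factor gene Hlf was 11.8-fold (9.46 to 14.7) lower, Mecom 2.65-fold (2.35 to 3.0) lower and Procr, which encodes the surface marker CD201, 4.21-fold (2.73 to 6.61) lower. The higher members were Ifitm1 at 3.33-fold (3.21 to 3.45), which alone took 55.6% of the list's SCF+TPO UMIs, and Slamf1, which encodes CD150, at 4.0-fold (2.5 to 6.74), or 2.47-fold without 1 SCF+TPO cell. With every cell weighted equally Hlf was 21-fold and Procr 11.2-fold lower, and Slamf1 1.87-fold higher.

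In the cytokine feedback list of SCF+TPO over SCF, 10 of 16 measured members were higher and 1 lower, with a summed ratio of 1.4 (1.35 to 1.45) and a median at percentile 98.1. Socs2, a feedback inhibitor of cytokine receptors, stood at 218 CPM against 13.6, 16.1-fold (12.2 to 21.6) higher, or 7.21-fold with every cell weighted equally. The kinase gene Pim1 was 7.47-fold (6.05 to 9.31) higher and Socs3 3.64-fold (1.42 to 11.9) higher, or 17.8-fold for Socs3 without 1 SCF cell, whereas no difference in Cish was detectable at this depth, at a ratio of 1.23 (0.587 to 2.76). Thinned, Socs2 was detected in 22 of 37 SCF+TPO cells (59.5%) and 8 of 41 SCF cells (19.5%), against 68.2% and 42.9% unthinned. Immediate early and heat shock genes were 1.92-fold (1.87 to 1.97) higher, with 9 of 14 members higher, 3 lower and a median at percentile 99.6. Among them the transcription factor gene Fos was 14-fold (9.29 to 21.9) higher, or 22.1-fold with every cell weighted equally, and the chaperone gene Hsp90aa1 2.04-fold (1.96 to 2.13) higher.

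Interferon response genes were 2.22-fold (2.11 to 2.34) lower in SCF+TPO, with 15 of 19 measured members lower, 0 higher and a median at percentile 0. Irf7, a transcription factor of that response, was 54.3-fold (20.6 to 203) lower, or 13-fold with every cell weighted equally. Isg15 was 2.71-fold (1.61 to 4.61) lower, but 1.37-fold without 1 SCF cell and 1.25-fold with equal weights. Quiescence and cell cycle inhibitor genes were 1.55-fold (1.49 to 1.61) lower, with 6 of 17 members lower, 4 higher and a median at percentile 16.7. However, their ratio was 0.841 with equal weights, 0.692 without the richest cells, 0.694 thinned and 0.913 by the median of members, each less than 1.5-fold. The cyclin-dependent kinase inhibitor genes Cdkn1a and Cdkn1c were 7.65-fold (6.68 to 8.78) and 51-fold (19.3 to 190) lower, or 4.81-fold and 14.4-fold with equal weights, and Cdkn1c 33.6-fold without 1 SCF cell. Cholesterol synthesis genes were lower in 11 of 23 members and higher in 0, at a ratio of 0.708 (0.689 to 0.727) and percentile 0.175.

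Several lists divided within themselves. The monocyte list had a summed ratio of 0.669 (0.637 to 0.701), with its most abundant gene Lyz2 2.67-fold (2.48 to 2.87) lower. Yet 8 of 13 measured members were higher and 3 lower. The median log2 ratio was 2.26 (percentile 99.96), or 2.41 with genes at 0 set to the bound of 3 counts. Irf8, a transcription factor of the monocyte lineage, was 21.6-fold (10.8 to 50.4) higher and the receptor gene Csf1r 12-fold (4.98 to 37.5) higher, but without the SCF+TPO cell richest in each the folds were 10.9-fold and 5.0-fold. Mast cell and basophil genes gave 0.671 (0.651 to 0.692), with 4 of 9 members higher, including Mcpt8 at 24.4-fold (16 to 39.1), or 9.21-fold without 1 SCF+TPO cell and 12.2-fold with equal weights, 3 lower and a median at percentile 18.1. Srgn, a lower member, held 72.5% of that list's UMIs in SCF+TPO and 79% in SCF, so the sum mostly follows this gene. Erythroid genes were 1.53-fold (1.49 to 1.57) lower, with 6 of 15 members lower, including the carbonic anhydrase gene Car2 at 4.95-fold (4.68 to 5.24), 4 higher and a median at percentile 9.45. With every cell weighted equally the erythroid ratio was 1.48, on the other side of 1, and thinned it was 0.812, less than 1.5-fold. With at least 2000 genes per cell, which left out 7 SCF+TPO and 0 SCF cells, the erythroid ratio was 0.623. Neutrophil late granule genes were 3.55-fold (3.34 to 3.77) lower, with 9 of 11 members lower and 2 higher, but 1 SCF cell held 69.8% of the SCF UMIs of the list, and equal weighting gave 3.11 in place of 0.282, while without the richest cells the ratio was 0.764. With at least 2000 genes per cell the late granule ratio was 0.243. Eosinophil genes, 8.15-fold (2.62 to 40.9) higher, had Prg2 as the 1 measured member, with 45 UMIs in SCF+TPO and 3 in SCF, and gave 44.3 with equal weights. Lymphoid genes gave 0.944 (0.89 to 1.0) in sum, but 7 of 11 members were higher and 2 lower. Among the higher were Flt3 at 4.52-fold (2.35 to 9.77) and Satb1 at 6.19-fold (4.0 to 10.1), or 10.4-fold for Satb1 with equal weights. The lymphoid median log2 ratio was 2.12 (percentile 99.8), or 2.18 with genes at 0 set to the bound of 3 counts.

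Other lists differed by less than 1.5-fold between SCF+TPO and SCF. Dendritic cell genes gave 0.855 (0.812 to 0.901), stromal and endothelial genes 1.3 (1.09 to 1.55) and cytokine receptor genes 0.721 (0.694 to 0.749). S phase genes gave 1.16 (1.14 to 1.19), and G2 and M phase genes 1.05 (1.03 to 1.06), although 13 of 32 of the latter, among them the proliferation marker Mki67 at 2.06-fold (1.82 to 2.32), were over 1.5-fold higher and 1 lower. As background for the member counts of SCF+TPO over SCF, 32.5% of 10142 measured protein coding genes were over 1.5-fold higher and 23.4% lower. The count of 13 of 32 is therefore not read as a cell cycle result. Glycolysis gave 0.965 (0.95 to 0.981), oxidative phosphorylation 1.15 (1.14 to 1.16) and ribosomal protein genes 0.935 (0.931 to 0.939). Mitochondrial transcripts gave 1.13 (1.12 to 1.14) and p53 and apoptosis genes 0.776 (0.747 to 0.806). The median log2 ratio of members was positive, against a summed ratio under 1, for dendritic cell (0.06), cytokine receptor (0.12) and glycolysis genes (0.02). The median log2 ratio of all 11593 genes with at least 30 UMIs was 0.17, so that a typical gene was slightly higher in SCF+TPO. TMM scaling brought this median to 0.04. Its log2 shift of -0.13 is less than 1.5-fold, so it could not turn the direction of a list that differed by over 1.5-fold.

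By the ranking by interval bound, 10 of the 12 genes that stood highest in SCF+TPO over SCF were annotated pseudogenes or predicted genes, whose reads can be shared with near-identical copies, so that their values are uncertain. Gm9800 and Gm11687 were examples, at 29.9-fold (21.7 to 42.3) and 25.1-fold (18.5 to 35), or 50.7-fold and 47.6-fold with equal weights. Annotated pseudogenes took 2.5% of the UMIs in SCF+TPO, 1.48% in SCF and 1.27% in SCF+G-CSF, and exceeded 5% of the UMIs of 12 SCF+TPO cells. The other 2 genes were Mpo and Pwwp2a, which had 173 UMIs in SCF+TPO and 0 in SCF, at least 30-fold higher. Without pseudogenes and predicted genes, a choice made after the values were seen, Clec12a at 34-fold (17.8 to 74.7), Cd48 at 24.7-fold (16.4 to 39.1) and Plac8 at 17.3-fold (13.7 to 22.2) ranked among the first, and Clec12a was 22.5-fold higher without 1 SCF+TPO cell. With equal weights Cd48 was 8.64-fold and Plac8 9.02-fold higher. In the other direction Tinagl1, which encodes a matrix glycoprotein, was 57.3-fold (37.8 to 91) lower in SCF+TPO. Traf1 was 57.7-fold (24.2 to 180) lower, Ptn, the gene of the growth factor pleiotrophin, 27.5-fold (18.8 to 42) lower and Ndn 26.1-fold (17.9 to 39.4) lower. With equal weights Tinagl1 was 20.7-fold, Traf1 37.4-fold, Ptn 13.5-fold and Ndn 51.9-fold lower. Tinagl1 (ENSMUSG00000028776.14) lies on chromosome 4 from 130164454 to 130175122.

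Transcripts of the SCF+TPO cells were also found at low level in SCF cells of the same library. Among 37 genes with at least 200 UMIs in SCF+TPO and at most 1 in SCF+G-CSF, none was at 0 in SCF, and the median SCF value was 0.0441 of the SCF+TPO value. The ratios ranged from 0.00805 to 0.173. Pwwp2a, with 173 UMIs in SCF+TPO and so under that limit, had 0 in SCF. Of these 37 genes, 25 were processed pseudogenes, whose values are uncertain, and 11 were protein coding. Named genes with a ratio within 2-fold of that median were Mpo, itself the median gene, Ctsg, Ms4a3, Socs2, Fos, Irf8, Csf1r, Mcpt8, Clec12a, Cd48, Plac8, Gm9800 and Gm11687. Of these, Mpo, Ctsg and Plac8 were among the 37 genes that set the median, and the others were not. For the others a ratio near the median restates the fold, and it cannot tell whether the SCF level is expression. If the SCF level of these named genes is not expression, the folds of SCF+TPO over SCF given for them are lower bounds. The level of SCF transcripts in SCF+TPO cells was not estimated in this way. Mpo had a UMI in 57.1% of SCF cells unthinned and 17.1% thinned, against 84.1% and 45.9% of SCF+TPO cells and 0 of 48 SCF+G-CSF cells, where the exact limit of 7.4% is for cells with a UMI at these unequal depths, not for cells that express the gene. Whether low shares of such genes in SCF cells are expression is left open, so they are not read as expression. With every cell weighted equally, 14 of 42 gene folds printed for SCF+TPO over SCF became over 1.5 times smaller and 8 larger. Without the richest cell of the condition with the lower value, folds over 1.5 times larger were, besides Socs3, Slamf1 at 13.2-fold, Flt3 at 8.91-fold, Clec12a at 59.1-fold, Isg15 at 6.17-fold, Ppbp at 25.8-fold, Irf7 at 108-fold, Traf1 at 143-fold and Cdkn1c at 187-fold.

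**Figure D1:**
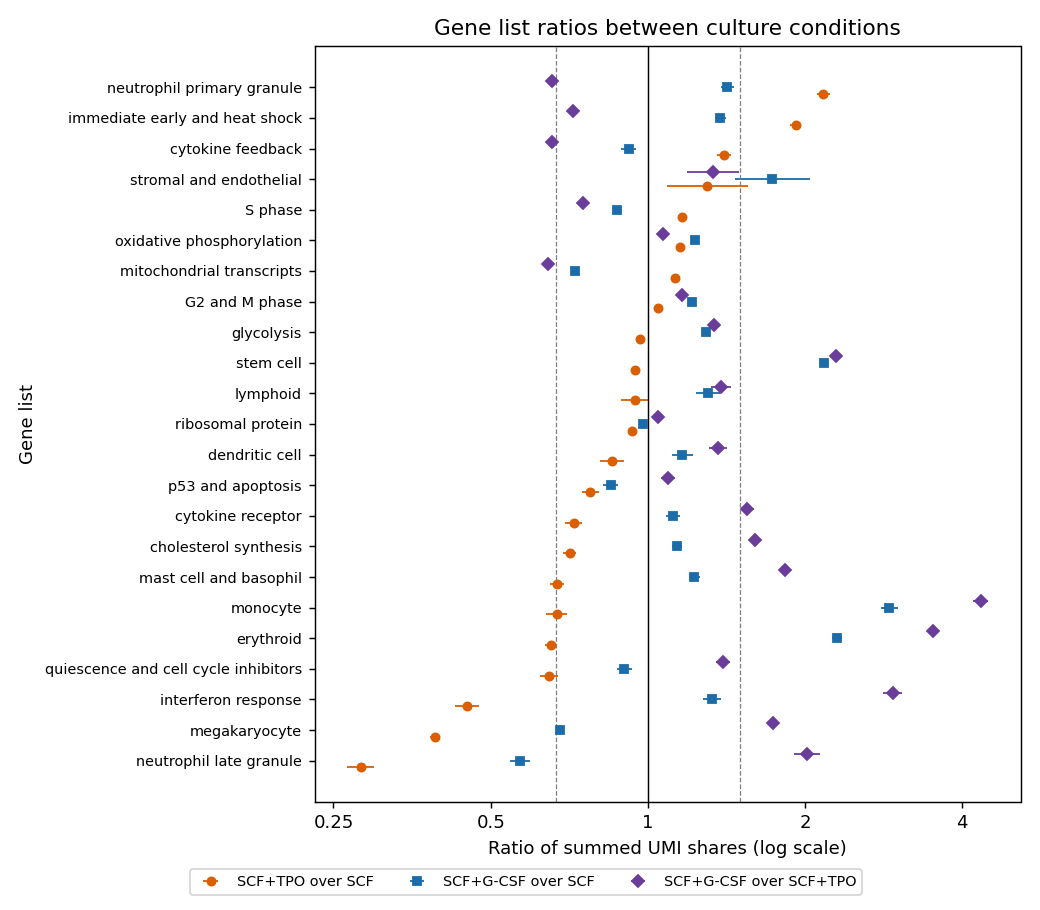
Ratio of summed UMI shares of each gene list on a log axis for the 3 comparisons, with exact 95% intervals for counting error and dashed lines at 1.5-fold in both directions. The megakaryocyte list lies at 0.391 in SCF+TPO over SCF, and the monocyte list at 4.34 in SCF+G-CSF over SCF+TPO.

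The comparison of SCF+G-CSF with SCF asked what G-CSF adds to SCF. Monocyte genes were higher in SCF+G-CSF, at 2282 against 786 CPM, 2.9-fold (2.8 to 3.01), with 8 of 11 measured members higher and 1 lower. The lysosomal gene Cd68 was 26.7-fold (18 to 41.3) higher and the lysozyme gene Lyz2 2.99-fold (2.84 to 3.14) higher. Ctss, which encodes cathepsin S, had 879 UMIs against 3, 92.5-fold (31.6 to 450) higher, or 44.4-fold with every cell weighted equally, and Tgfbi 1281 against 0, at least 135-fold higher. The median log2 ratio of the list was 4.71, at percentile 100. With genes at 0 set to the bound of 3 counts it was 2.31, for which no percentile was computed. The conditions lay in different libraries, so the library and G-CSF cannot be told apart.

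The receptor gene Csf3r stood at 68.1 CPM in SCF+G-CSF and 2.87 in SCF, 23.7-fold (13.2 to 47.8) higher, and after thinning it was detected in 19 of 42 SCF+G-CSF cells (45.2%) and 2 of 41 SCF cells (4.88%), against 81.2% and 11.9% unthinned. Socs3, a feedback inhibitor of the G-CSF receptor, was 24.7-fold (10.5 to 76.5) higher, or 121-fold without 1 SCF cell, and Pim1 3.68-fold (2.98 to 4.6) higher. The cytokine feedback list held 8 higher and 4 lower of 19 measured members, with a summed ratio of 0.919 (0.889 to 0.949) and a median log2 ratio of 0.44 (percentile 98.5). One of the lower members was Socs2, whose SCF level lay near that of SCF+TPO transcripts found at low level in SCF cells, so that no fold is given. The cytokine receptor list held 8 higher and 4 lower of 19, at a ratio of 1.12 (1.08 to 1.15). Mpl was 1.92-fold (1.79 to 2.06) lower and Kit 1.64-fold (1.46 to 1.84) lower. Csf3r (ENSMUSG00000028859.14) lies on chromosome 4 from 126024550 to 126044440.

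Stem cell genes took a 2.17-fold (2.14 to 2.21) larger share in SCF+G-CSF, but 9 of 27 members were higher and 9 lower. The median log2 ratio was -0.28 (percentile 1.28). Ifitm1 alone held 43.6% of the list's UMIs in SCF+G-CSF and 15.8% in SCF, so much of the larger sum is this gene. Ifitm1 at 5.99-fold (5.79 to 6.21), Ly6a, which encodes the Sca-1 antigen, at 3.97-fold (3.79 to 4.16) and Procr at 6.24-fold (4.91 to 8.05), or 3.72-fold with every cell weighted equally, were higher, whereas Mecom was 2.82-fold (2.53 to 3.15) lower and Hlf 2.36-fold (2.12 to 2.63) lower. Thinned, Procr was detected in 71.4% of SCF+G-CSF and 14.6% of SCF cells, against 85.4% and 23.8% unthinned. Megakaryocyte genes gave 0.68 (0.668 to 0.692), with 11 of 23 members lower, 1 higher and a median at percentile 0.23. In that list Itga2b, which encodes CD41, was 2.32-fold (1.93 to 2.78) lower, but 1.3-fold with every cell weighted equally, and Vwf 2.2-fold (1.73 to 2.79) lower.

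The erythroid list was 2.3-fold (2.25 to 2.35) higher in sum, through 1 abundant gene. Hbb-bt, an adult beta globin gene, stood at 4638 CPM in SCF+G-CSF and 314 in SCF, 14.8-fold (13.9 to 15.6) higher, or 27-fold with every cell weighted equally. Thinned, Hbb-bt was detected in 100% of SCF+G-CSF cells and 41.5% of SCF cells, against 100% and 66.7% unthinned. By contrast 11 of 14 measured erythroid members were lower, with a median log2 ratio of -3.31 (percentile 0). The alpha globin gene Hba-a1 was 22.1-fold (16.8 to 29.4) lower and the beta globin gene Hbb-bs 12.6-fold (10.7 to 15) lower. With equal weights Hba-a1 was 5.49-fold lower and the Hbb-bs ratio was 1.64. Per SCF+G-CSF cell, however, Hbb-bs had a median of 0 CPM and an upper quartile of 3.94, against a median of 26.7 in SCF. The ratio of 1.64 thus rests on SCF+G-CSF cells above that quartile. Values of these globin genes are uncertain, because near-identical copies can share reads. Hbb-bt (ENSMUSG00000073940.3) lies on chromosome 7 from 103812524 to 103813996.

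Neutrophil primary granule genes gave 1.42 (1.38 to 1.46), with 3 of 13 members higher, including Prtn3 at 4.88-fold (4.4 to 5.44), and 4 lower. Gstm1, the most abundant member, held 33.8% of the list's UMIs in SCF+G-CSF and 37% in SCF. Mpo and Ctsg are among the 4 lower members, although it is open whether their low SCF level is expression. Both had no UMI in SCF+G-CSF, where 3 counts correspond to 0.247 CPM. Neutrophil late granule genes were 1.76-fold (1.68 to 1.84) lower in sum, with 6 of 11 members lower and 5 higher. Ngp, a neutrophil granule protein gene, had 440 UMIs in SCF and 0 in SCF+G-CSF, at least 464-fold lower, but 1 SCF cell held 90.7% of them, and without it the bound was 45.8-fold. Without the cell of each condition richest in the list, the late granule ratio was 1.6, on the other side of 1, and it was 0.805 with equal weights and 0.873 thinned, less than 1.5-fold.

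By the same ranking, Cd74, which encodes the invariant chain of class II antigen presentation, had 2411 UMIs in SCF+G-CSF and 0 in SCF, at least 254-fold higher. Wfdc17, a secreted protease inhibitor gene, was 57.1-fold (49.8 to 65.7) higher and Cd53 92.1-fold (50 to 192) higher, or 31.9-fold with every cell weighted equally. Gm15987, an antisense gene whose values are uncertain, was 1 of the 12. Among the genes lower in SCF+G-CSF, Bcl2, an inhibitor of apoptosis, was 27.6-fold (18.2 to 43.6) lower, the receptor gene Egfr 31.4-fold (17.3 to 62.5) lower and Ptn 15.1-fold (11.9 to 19.4) lower. Leaving out the richest cell of the condition with the lower value gave over 1.5 times larger folds for Csf3r at 35.7-fold, Hbb-bt at 26.4-fold, Cd68 at 54.2-fold, Ctss at 275-fold, Bcl2 at 47.5-fold and Ptn at 52.9-fold, besides Socs3. Cd74 (ENSMUSG00000024610.14) lies on chromosome 18 from 60803848 to 60812652.

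In SCF+G-CSF over SCF, mast cell and basophil genes gave 1.23 (1.2 to 1.26), lymphoid 1.3 (1.24 to 1.38) and dendritic cell genes 1.16 (1.11 to 1.22). Srgn held 64.4% of the UMIs of the mast cell and basophil list in SCF+G-CSF and 79% in SCF. Stromal and endothelial genes gave 1.73 (1.47 to 2.04) over 4 measured members, including Pecam1 at 3.03-fold (2.3 to 4.06), but 1.17 with equal weights and 1.34 thinned, less than 1.5-fold. S phase gave 0.873 (0.857 to 0.889), G2 and M phase 1.22 (1.2 to 1.23) and quiescence and cell cycle inhibitor genes 0.901 (0.871 to 0.932). Interferon response genes gave 1.32 (1.27 to 1.38), with 8 of 20 members higher, 2 lower and a median at percentile 99.4. Glycolysis gave 1.29 (1.28 to 1.31), oxidative phosphorylation 1.23 (1.22 to 1.24), cholesterol synthesis 1.14 (1.11 to 1.16) and ribosomal protein genes 0.978 (0.974 to 0.981). Mitochondrial transcripts gave 0.726 (0.72 to 0.732), immediate early and heat shock genes 1.38 (1.35 to 1.41) and p53 and apoptosis genes 0.849 (0.82 to 0.878). Eosinophil genes gave 2.53 (0.767 to 13.1) with no member of 30 UMIs. The median log2 ratio of members differed in sign from the sum for mast cell and basophil (-0.19), dendritic cell (-0.28), ribosomal protein (0.01) and p53 and apoptosis genes (0.09). Over all genes the median log2 ratio, from 11662 genes, was -0.03.

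**Figure D2:**
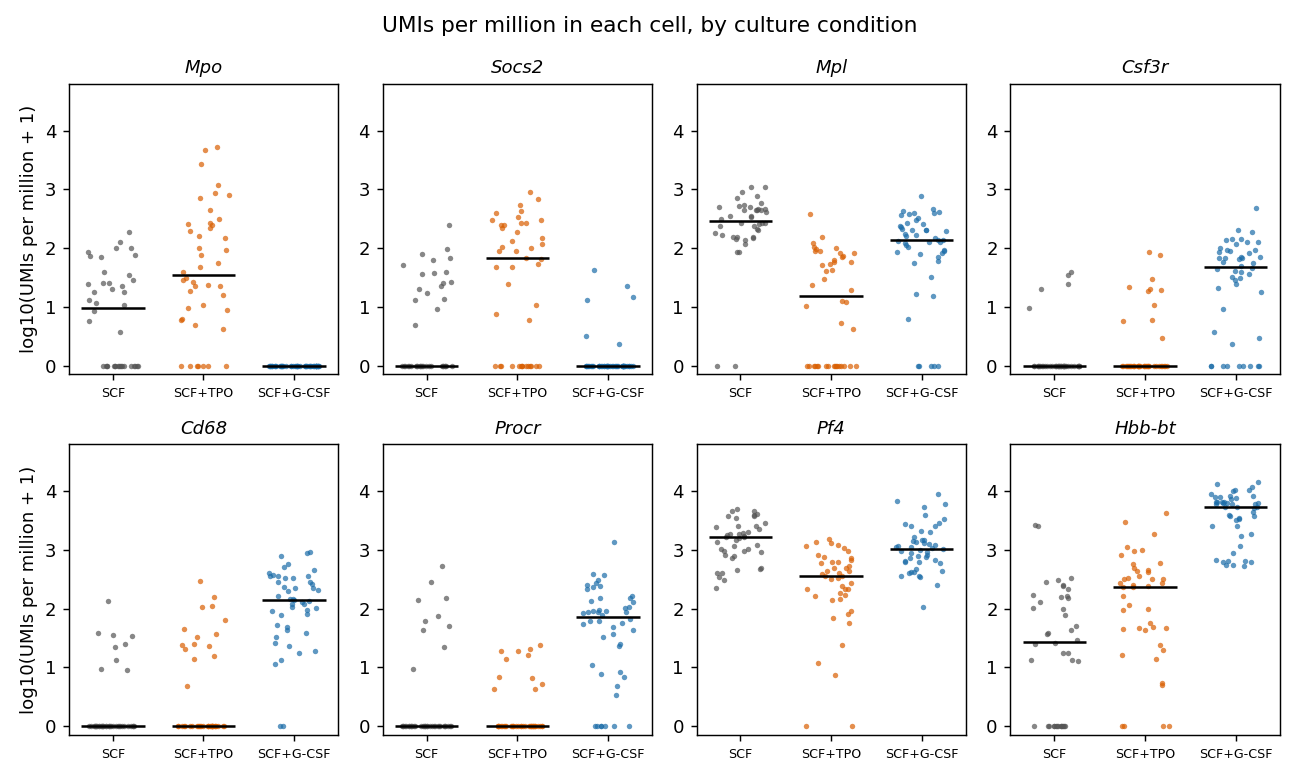
UMIs of 8 genes in each cell, as log10 of the CPM of the cell plus 1, in the 42 SCF, 44 SCF+TPO and 48 SCF+G-CSF cells, with 1 point per cell and a black line at the median. Mpo is at 0 in every SCF+G-CSF cell, and Hbb-bt is above 0 in all 48 of them, while depth per cell differs between conditions.

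The comparison of SCF+G-CSF with SCF+TPO set both added cytokines side by side, again across libraries. Monocyte genes were 4.34-fold (4.2 to 4.49) higher in SCF+G-CSF, interferon response genes 2.94-fold (2.82 to 3.07) and stem cell genes 2.3-fold (2.27 to 2.32). In the interferon list 17 of 20 measured members were higher and 0 lower (percentile 100), with Irf7 at 97.47-fold (37.9 to 359) and Isg15 at 7.56-fold (5.1 to 11.6), or 21-fold and 2.86-fold with every cell weighted equally. In the stem cell list 18 of 27 were higher and 3 lower (percentile 100), with Procr at 26.2-fold (18.5 to 38.5), or 41.5-fold with equal weights, and Ly6a at 15.4-fold (14.4 to 16.4). In the monocyte list 10 of 16 members were higher and 5 lower (percentile 99.8), with Lyz2 7.96-fold (7.52 to 8.43) higher and Csf1r 21-fold (10.7 to 47.2) lower, or 8.8-fold without 1 SCF+TPO cell, 184-fold without 1 SCF+G-CSF cell and 43.2-fold with equal weights. Cholesterol synthesis genes were 1.61-fold (1.57 to 1.64) higher, in 13 of 23 members against 2 lower (percentile 99.99).

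Neutrophil primary granule genes were 1.53-fold (1.5 to 1.55) lower in SCF+G-CSF, with 10 of 16 members lower and 4 higher (percentile 0.070). Gstm1, a higher member, held 33.8% of the list's UMIs in SCF+G-CSF and 4.03% in SCF+TPO. Mpo was at least 2299-fold and Ctsg at least 1213-fold lower, the latter at least 800-fold without 1 SCF+TPO cell, while Prtn3 was nearly level at 1.08 (1.04 to 1.13). The list ratio was less than 1.5-fold with TMM factors (0.767), size factors, equal weights, without the richest cells and thinned (0.806 at most). Cytokine feedback genes were 1.52-fold (1.49 to 1.56) lower, in 8 of 19 members against 5 higher (percentile 22), and less than 1.5-fold with TMM factors (0.769), size factors, equal weights, without the richest cells, thinned and by the median (0.776). Socs2 was 126-fold (82.1 to 204) lower, or 75.8-fold with equal weights, and Socs3 6.78-fold (4.8 to 9.88) higher. Pim1 was 2.03-fold (1.87 to 2.2) lower, but with every cell weighted equally its ratio was 1.02. Cytokine receptor genes were 1.55-fold (1.51 to 1.6) higher, with Csf3r at 6.12-fold (4.88 to 7.78), or 9.96-fold with equal weights, and Mpl at 3.07-fold (2.77 to 3.41), but the median ratio of members was 1.09.

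Megakaryocyte genes were 1.74-fold (1.71 to 1.77) higher in SCF+G-CSF, with 9 of 22 members higher and 9 lower and a median ratio of members of 1.12. Pf4 was 2.9-fold (2.8 to 3.0) higher and Itga2b 3.07-fold (2.66 to 3.56) lower, or 1.97-fold with equal weights. Erythroid genes were 3.52-fold (3.46 to 3.59) higher in sum, or 1.87-fold with equal weights, with Hbb-bt at 17.7-fold (16.9 to 18.5), or 11.6-fold with equal weights, while 8 of 12 members were lower. Mast cell and basophil genes were 1.83-fold (1.79 to 1.87) higher, although 5 of 9 members, among them Mcpt8 at 38.7-fold (28.6 to 53.5), or 14.6-fold without 1 SCF+TPO cell and 532-fold without 1 SCF+G-CSF cell, were lower. Srgn, a higher member, held 64.4% of that list's UMIs in SCF+G-CSF and 72.5% in SCF+TPO. Neutrophil late granule genes were 2.02-fold (1.91 to 2.13) higher, with 4 of 11 members higher and 6 lower. They gave 0.259 with every cell weighted equally and 2.34 with at least 2000 genes per cell. The median ratio of members was 0.481 for erythroid, 0.605 for mast cell and basophil and 0.408 for late granule genes, on the other side of 1 from their sums. Eosinophil genes were 3.22-fold (1.93 to 5.51) lower, at a ratio of 0.0403 with equal weights and 0.0564 without the richest cells. In SCF+TPO Prg2, the 1 measured member, held 95.7% of the list's UMIs, and 1 cell held 55.3%. In SCF+G-CSF Alox15 held 100%, and 1 cell held 91.7%. The ratio therefore sets different genes of few cells against each other. Mitochondrial transcripts were 1.55-fold (1.54 to 1.56) lower, but 0.754 with TMM factors, 0.747 with size factors and 0.711 by the median, less than 1.5-fold. With equal weights the ratio was 0.506.

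The lists that differed by less than 1.5-fold here were lymphoid at 1.38 (1.32 to 1.44), dendritic cell at 1.36 (1.31 to 1.41) and stromal and endothelial genes at 1.33 (1.19 to 1.49). The median log2 ratios of lymphoid (-0.90) and stromal and endothelial members (-2.01) had the opposite sign to their sums. S phase gave 0.75 (0.74 to 0.761), G2 and M phase 1.16 (1.15 to 1.18) and quiescence and cell cycle inhibitor genes 1.4 (1.35 to 1.44). Glycolysis gave 1.34 (1.33 to 1.36), oxidative phosphorylation 1.07 (1.06 to 1.08) and ribosomal protein genes 1.05 (1.04 to 1.05). Immediate early and heat shock genes gave 0.717 (0.707 to 0.728), with Fos 75.7-fold (44.8 to 139) lower, 521-fold without 1 SCF+G-CSF cell and 165-fold with equal weights, and p53 and apoptosis genes 1.09 (1.06 to 1.13). By the ranking, Tgfbi was at least 259-fold higher in SCF+G-CSF and Pcp4l1 80.9-fold (59.4 to 113) higher. Irf7 at 194-fold, Isg15 at 17.2-fold, Csf3r at 10.1-fold and Pcp4l1 at 122-fold were over 1.5 times larger without 1 SCF+TPO cell. Of the 12 genes that stood lowest, 8 were annotated pseudogenes and are uncertain, and the others were Mpo, Ctsg, Rpl39l and Plac8, which had 1 UMI in SCF+G-CSF and 2429 in SCF+TPO. Over all genes the median log2 ratio, from 12533 genes, was -0.17.

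Clustering of the 134 cells gave 8 clusters, and 94.8% of the cells (127 of 134, exact 95% interval 89.5 to 97.9) belonged to the commonest condition of their cluster. The largest condition made up 35.8% of all cells. That is not the share that random labels would give, since the commonest condition is taken anew in each cluster, and no such share was computed. Clusters were left unnamed and their sizes were not compared, since a cluster of 1 library may be that library and not a cell type.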

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

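Leaving out cells with over 5% pseudogene UMIs, pseudogenes and predicted genes from the total, or the cell richest in a named gene was chosen after seeing the data. Tests with DESeq2 or edgeR, and leaving out animals or cultures, were not run, since the cell table names none, and no paired analysis was possible because each condition is a single sample. Of the values of lists over 1.5-fold under the alternatives, the sex-linked list included, 103 of 105 (SCF+TPO over SCF), 68 of 71 (SCF+G-CSF over SCF) and 160 of 164 (SCF+G-CSF over SCF+TPO) kept their side of 1. Among named genes 500 of 502 values with TMM factors or equal weights did. The others were Hbb-bs in SCF+G-CSF over SCF (1.64) and Pim1 in SCF+G-CSF over SCF+TPO (1.02), with equal weights. TMM and size factors shifted log2 ratios by at most 0.23, less than 1.5-fold. Values with these factors could therefore not change side, and their part of the counts shows no robustness. With equal weights 6 of 25 printed gene folds of SCF+G-CSF over SCF and 6 of 17 of SCF+G-CSF over SCF+TPO became over 1.5 times smaller, and 1 and 4 larger. Of the printed gene folds over 1.5-fold with an interval that excluded 1, without the richest cell of either condition 10 of 43 (SCF+TPO over SCF), 1 of 28 (SCF+G-CSF over SCF) and 3 of 20 (SCF+G-CSF over SCF+TPO) became over 1.5 times smaller, and 9, 7 and 7 larger in at least 1 case of leaving out a cell. None of these changed side of 1, whereas Cish in SCF+TPO over SCF, not over 1.5-fold, went from 1.23 (0.587 to 2.76) to 0.98, and Itgb3 and Isg15 in SCF+TPO over SCF fell under 1.5-fold. The share of cells in the commonest condition of their cluster was 92.5% to 94.8% over the cluster settings. Depth limits genes of few UMIs most in SCF. The causes of the shifts listed in this part were not tested, except where leaving out a cell or changing the weights shows them.

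The interferon response ratio moved over 1.5 times by the median, to 0.226 (SCF+TPO over SCF) and 5.38 (SCF+G-CSF over SCF+TPO). Among lists over 1.5-fold, signs turned in these cases. With equal weights for cells the late granule ratio was 3.11 (SCF+TPO over SCF) and 0.259 (SCF+G-CSF over SCF+TPO), and the erythroid ratio 1.48 (SCF+TPO over SCF). Without the richest cells the late granule ratio of SCF+G-CSF over SCF was 1.6. By the median of members, the ratios were 0.823 for stem cell and 0.101 for erythroid genes (SCF+G-CSF over SCF), and 0.408 for late granule, 0.605 for mast cell and basophil and 0.481 for erythroid genes (SCF+G-CSF over SCF+TPO).

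For SCF+TPO over SCF, the megakaryocyte ratio (0.391) moved to 0.358 with TMM factors, 0.36 with size factors, 0.405 without the richest cells, 0.377 thinned and 0.527 by the median. The primary granule ratio (2.17) moved to 1.99 with TMM factors, 2.0 with size factors, 1.64 with equal weights, 1.86 without the richest cells, 1.78 thinned, 3.67 by the median and 2.27 without pseudogene-rich cells. For SCF+G-CSF over SCF, the stem cell ratio (2.17) moved to 2.33 with TMM factors, 2.32 with size factors, 2.14 with equal weights, 2.1 thinned and 2.14 without abundant genes in the total. The monocyte ratio (2.9) moved to 3.11 with TMM factors, 3.1 with size factors, 2.74 without the richest cells, 3.09 thinned and 26.2 by the median, which rests on genes at 0 in SCF (log2 4.71, against 2.31 with these at the bound of 3 counts). For SCF+G-CSF over SCF+TPO, the primary granule ratio (0.655) moved to 0.767 with TMM factors, 0.76 with size factors, 0.806 with equal weights, 0.698 without the richest cells, 0.732 thinned, 0.418 by the median and 0.627 without pseudogene-rich cells. The monocyte ratio (4.34) moved to 5.09 with TMM factors, 5.04 with size factors, 4.71 with equal weights, 2.06 by the median and 4.16 without pseudogene-rich cells.

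Of 24 lists, 3 were over 1.5-fold higher and 5 lower in SCF+TPO over SCF, against 3 higher and 9 lower with TMM factors, 9 lower with size factors, and 5 higher by the median. In SCF+G-CSF over SCF 4 were higher and 1 lower, against 6 and 1 with TMM factors, 2 and 3 by the median, and 0 lower with equal weights or thinned. In SCF+G-CSF over SCF+TPO 9 were higher and 4 lower, against 14 and 1 with TMM or size factors, 4 and 7 by the median, 2 lower without the richest cells and 1 lower thinned. TMM factors shifted log2 ratios by -0.13, 0.10 and 0.23 in these 3 comparisons.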

Other observations

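The tests of exchange between barcodes, of SCF cells that express the genes, and both tests on Hbb-bt were chosen after their results were seen.

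Transcripts of Y-linked genes lay in some SCF+TPO cells. Summed over 4 Y-linked genes, 25 UMIs lay in 8 of 44 SCF+TPO cells, and 0 in the 42 SCF and 0 in the 48 SCF+G-CSF cells. Xist, transcribed from the inactive X chromosome, had a UMI in 36 SCF+TPO, 34 SCF and 43 SCF+G-CSF cells. Of the 8 SCF+TPO cells with a Y-linked UMI, 2 had no Xist UMI, and the others had both. The cause was not tested. Since the cell table names no animal, a difference in donors between SCF+TPO and SCF cannot be told apart from an effect of TPO. The sex-linked list, with Xist as its 1 measured member, gave ratios of 2.08 (1.87 to 2.31) for SCF+TPO over SCF, 0.595 (0.53 to 0.668) for SCF+G-CSF over SCF and 0.286 (0.263 to 0.31) for SCF+G-CSF over SCF+TPO. For SCF+G-CSF over SCF it was 0.783 with equal weights and 0.773 thinned, less than 1.5-fold.

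The first pattern is the low level of SCF+TPO transcripts in SCF cells of the same library. With every condition at 3835796 UMIs, 54 genes with at least 100 UMIs in SCF+TPO had at most 1 in SCF+G-CSF, and 1 gene had at most 1 in SCF. The other pairs gave 7 genes (high in SCF, off in SCF+G-CSF), 8 (high in SCF+G-CSF, off in SCF), 6 (high in SCF+G-CSF, off in SCF+TPO) and, within the library, 1 (high in SCF, off in SCF+TPO). A single SCF cell that expresses these genes is argued against for the 20 of 37 genes with at least 10 SCF UMIs, since the top cell held a median of 21.4% of a gene's SCF UMIs. Exchange of UMIs between barcodes of the shared library stays open. Of the 37 genes, 81.1% had an SCF to SCF+TPO ratio within 2-fold of their median. That share cannot tell exchange from other causes, since no reference genes show what share would lie there without exchange. The ratios of the 37 genes ranged from 0.00805 to 0.173. Pwwp2a, with 173 UMIs in SCF+TPO and so not among them, had 0 in SCF. Several expressing SCF cells stay open, since the 5 richest held 54.5% of the pooled SCF UMIs of the 37 genes, 25 of them processed pseudogenes, while the 5 deepest held 30.8% of all SCF UMIs. A low true level in SCF cells was not tested.

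The second pattern is the higher share of pseudogenes in SCF+TPO than in SCF, 1.69-fold (1.68 to 1.71) over all annotated ones. As background, 32.5% of 10142 measured protein coding genes were over 1.5-fold higher in SCF+TPO. Reads of parent genes assigned to processed copies could raise most copies together, but 72.6% of 570 measured processed pseudogenes were over 1.5-fold higher, between the bounds set for and against it, so it stays open. Genomic DNA could also raise them, and olfactory receptor genes gave 1.42 (1.2 to 1.69), past the bound set for it. However, 1 SCF+TPO cell held 213 of their 516 UMIs, and without the richest cell of each condition, a step added after that result, the ratio was 1.12 (0.909 to 1.38), so this cannot be told apart either.

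The third pattern is the level of Hbb-bt in SCF+G-CSF cells. Red cells or their free RNA are argued against, because they hold both globin chains and SCF+G-CSF had 0.00121 alpha globin UMIs per Hbb-bt UMI, against 0.562 in SCF. Reads moved between the adult beta globin copies are argued against as the whole cause, because the sum of Hbb-bs and Hbb-bt was 9.42-fold that in SCF (8.99 to 9.86). An effect of G-CSF and an effect of the separate library cannot be told apart, since no other condition shares that library.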
